A study of Mus musculus with 4 samples.

How the data were processed

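The series holds 4 ChIP-seq libraries from primary mouse keratinocytes that carry the K14deltaNLef1 transgene and were infected with a lentivirus to overexpress Gata6, a zinc-finger transcription factor. Chromatin was immunoprecipitated with 2 different Gata6 antibodies (2 libraries, grouped here as Gata6 ChIP), with a Flag antibody as a negative control (1 library), and input DNA was sequenced as a further control (1 library). Per the labels' protocols, cells were grown on irradiated 3T3-J2 mouse fibroblast feeders, nuclei were sonicated, and size-selected libraries were sequenced on the Genome Analyzer. The same protocol text names complexes of a truncated Lef1 protein as the precipitated material, whereas the sample titles and antibody labels name Gata6 or Flag. The titles and antibody labels were followed. The genotype label of the first Gata6 library ends in a further letter N, and it was read as the same genotype.

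The table analysed is 1 list of 12137 peaks for the whole series, with no values per library. The submitters' processing notes name BWA, HOMER and the mouse build mm9, without versions or roles. Which lists were intersected, the minimum overlap, the peak-calling threshold and the use of the Flag and input libraries are not given in the sources used here. In the list as deposited by the authors, the score column is 0 in every row, and every row is on the plus strand, so neither carries peak strength or orientation. The deposited start and end coordinates were read as mm9 positions and are given 1-based. On 6 chromosomes the last peak lies beyond the last gene of a GRCm38 gene table, as it can where the builds differ in length. That table belongs to another build, so it was used for nothing else. No genome sequence, gene annotation or chromosome length of build mm9 was used here. As fixed before the data were examined, the tests that need them were therefore not run: shares of peaks in promoters, exons and introns, distances to transcription start sites, 24 gene lists and 25 sequence motifs. No gene is named for any peak.

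Each deposited peak name joins the chromosome to a whole number, and all 12137 names differ. What the number counts is not given in the sources used here, and it is called the name number below. Numbers between 1 and the highest one on a chromosome that occur in no listed name are called unlisted. An unlisted number can stand for an interval with no partner in another list or for one removed by an earlier filter, and these were not separated.

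Peaks were analysed by midpoint with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. Density was the number of peaks divided by the span from the first to the last peak of a chromosome. This density and its tests were chosen after the data were seen, since the design foresaw only counts where chromosome lengths of build mm9 were not at hand. The analyses of name numbers, of groups of peaks and of peaks with a neighbour were also chosen after the data were seen. Chromosomes were compared over 493 complete 5-Mb windows by 100000 two-sided permutations of windows between chromosomes, with Benjamini-Hochberg adjustment over the 20 chromosomes, and 95% intervals came from 10000 bootstrap draws of windows. Clustering was tested against 1000 random relocations of the midpoints within the chromosome's span, as designed, and after the data were seen also within each peak's own 5-Mb or 1-Mb window. The smallest two-sided p that 1000 relocations allow is 0.002. With all listed peaks relocated within chromosome spans, adjustment over the 9 measures of a setting left p = 0.002 of these permutation tests at 0.002. Peaks with and without a neighbour within 5 kb were compared by 10000 permutations within chromosomes. Unlisted numbers were placed on a chromosome where 2 listed peaks that follow each other in number also follow each other in position: the numbers between them were spread evenly between the midpoints. Shares carry 95% Wilson intervals, which cover counting error only. The regions named were the 5 1-Mb windows with most peaks, by a rule fixed before the data were examined. The same rule asked for the 5 widest peaks, which could not be chosen because 764 peaks share the largest width.

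The statistics were tested on simulated data. Among 20 sets of randomly placed peaks the clustering test called 1, and with 200 planted close pairs it called 20 of 20 and found a mean excess of 198.1 pairs. The window permutation called 0 chromosomes in 20 simulations without an effect and called a chromosome reduced to 25% of its density in 20 of 20. The simulated windows were drawn independently, so these runs do not show how the permutation behaves where neighbouring windows are alike. An exact binomial test over single peaks made 215 calls in 400 tests on further windows simulated in the same way without an effect, so the permutation of windows was used in its place. The comparison of clustered with isolated peaks called 2 of 20 sets without a difference and 20 of 20 with one planted. Its simulated values were drawn independently for each peak, so likeness between neighbouring peaks was not simulated. The placing of unlisted numbers found 16.2% of them in a 20-Mb segment that truly held 15.9%, and 61.4% where a planted segment truly held 70.8%. In this setting the placing understated a local excess. The simulated peaks were spread evenly and no planted interval was listed, so clustered peaks as in the data were not simulated. The closeness asked for at first was not reached with the planted segment, and the limit was then widened to allow for this understatement.

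The alternatives were autosomes only, merging of peaks within 1 kb, the wider peaks (the 6176 peaks of 143 bp or more), neighbour distances of 1 and 20 kb, windows shifted by 500 kb, and leaving out chromosome 10. The sequencing depth of each library is unknown from the peak list, and the spread between the libraries of the 2 antibodies could not be computed. All p-values therefore describe how peaks are placed within 1 list, and peaks are not replicates of the experiment.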

Results

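Binding sites of Gata6 were mapped by ChIP-seq in primary mouse keratinocytes from dorsal skin. The cells carried the K14deltaNLef1 transgene, which directs an N-terminally truncated form of the Wnt effector Lef1 to keratin 14-expressing epidermal cells, and they overexpressed Gata6 from a lentivirus. The design comprised 2 Gata6 libraries made with different antibodies, 1 Flag library as a negative control and 1 input library. The question named for the series was which genomic sites Gata6 occupies in these cells. The result available as data was a single overlap list of peaks on build mm9, so the libraries could not be compared with each other, and the comparisons below are between parts of the genome.

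The listed peaks covered 1.61 Mb on the 19 autosomes and chromosome X. Listed peaks were narrow, with a median width of 143 bp (interquartile range 120 to 157 bp) and a range of 1 to 166 bp. Widths here and below are those of the intervals in the overlap list, which does not hold the width of whole binding sites. The largest width, 166 bp, was shared by 764 peaks (6.29%), against 288 peaks of 165 bp. Of all peaks, 1106 (9.11%) were 83 bp wide or narrower, and 9 peaks were 1 bp wide.

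Gata6 peaks were spread over all autosomes but unevenly. Chromosome 11 carried the most, with 959 peaks or 8.09 per Mb of its span, followed by chromosome 19 with 7.36 per Mb and chromosome 6 with 6.37 per Mb. The sparsest autosomes were chromosome 14, with 301 peaks or 2.64 per Mb, and chromosome 12, with 350 peaks or 2.98 per Mb. Chromosome X carried 175 peaks or 1.09 per Mb, against 5.01 per Mb over the autosomes together, a 4.59-fold difference.

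Measured over 5-Mb windows, chromosome X held 5.03 ± 4.84 peaks per window (SD over 31 windows), against a mean of 24.7 on the other chromosomes (permutation of windows, adjusted p = 0.0002, from the smallest p that the permutations can give). Chromosome 11 held 39.2 ± 21.9 (SD over 23 windows) against 22.7 elsewhere (permutation, adjusted p = 0.0004). Chromosome 14 held 12.5 ± 9.22 (SD over 22 windows) against 24.0 elsewhere (permutation, adjusted p = 0.0118). Chromosomes 6 and 12 were also apart from the rest, with 31.3 ± 18.8 (SD over 28 windows) and 14.8 ± 10.6 (SD over 23 windows) peaks per window (permutation, adjusted p = 0.0452 for each). With autosomes only, chromosome 6 no longer passed (permutation, adjusted p = 0.148), whereas chromosomes 11, 12 and 14 did. For chromosome 19, with 34.6 ± 13.1 peaks per window over 11 windows, the difference did not pass after adjustment (permutation, adjusted p = 0.0874). These permutations take windows as independent. Likeness between neighbouring windows, not tested here, could make the p-values too small. The densities of chromosome X and of the autosomes are not corrected for copy number in these cells, for unassembled sequence or for the share of sequence to which reads can be mapped.

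**Figure D1:**
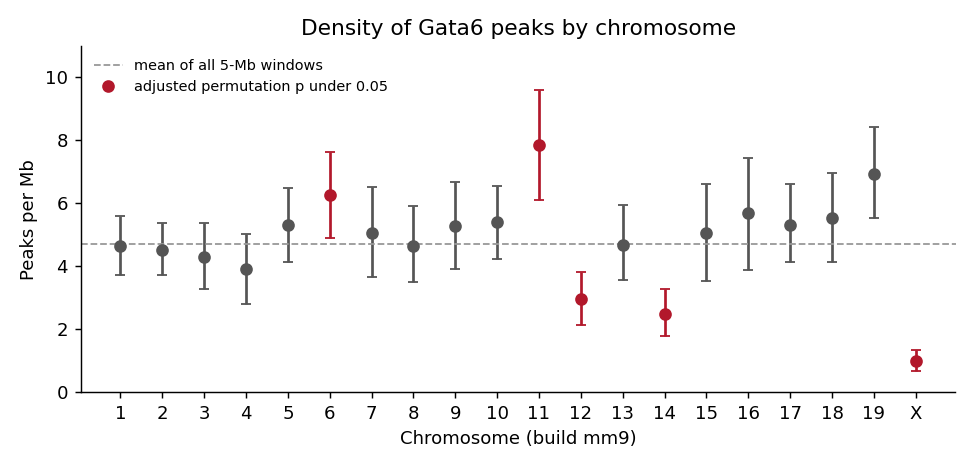
Peaks per Mb on each chromosome (points, mean of complete 5-Mb windows; bars, 95% bootstrap intervals over windows), with chromosomes whose adjusted permutation p was under 0.05 in red and the mean of all windows as a dashed line. Chromosomes 11 and 6 lie above the mean, and chromosomes 12, 14 and X lie below it.

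Neighbouring peaks lay close together. The median distance between neighbouring midpoints was 47.7 kb, against 135 kb after random relocation, and 2811 peaks (23.2%) had another peak within 5 kb. There were 1503 neighbouring pairs within 5 kb, against a mean of 313 (range 251 to 369) in 1000 relocations within chromosome spans, a 4.80-fold excess (permutation p = 0.002, the smallest that the relocations allow). The excess was 6.43-fold for pairs within 1 kb (409 pairs) and 3.22-fold for pairs within 20 kb (3867 pairs; permutation p = 0.002 for each). When each peak was moved only within its own 1-Mb window, the excess within 5 kb was 2.55-fold (permutation p = 0.002, adjusted p = 0.0036). The smallest distance between midpoints was 343 bp.

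**Figure D2:**
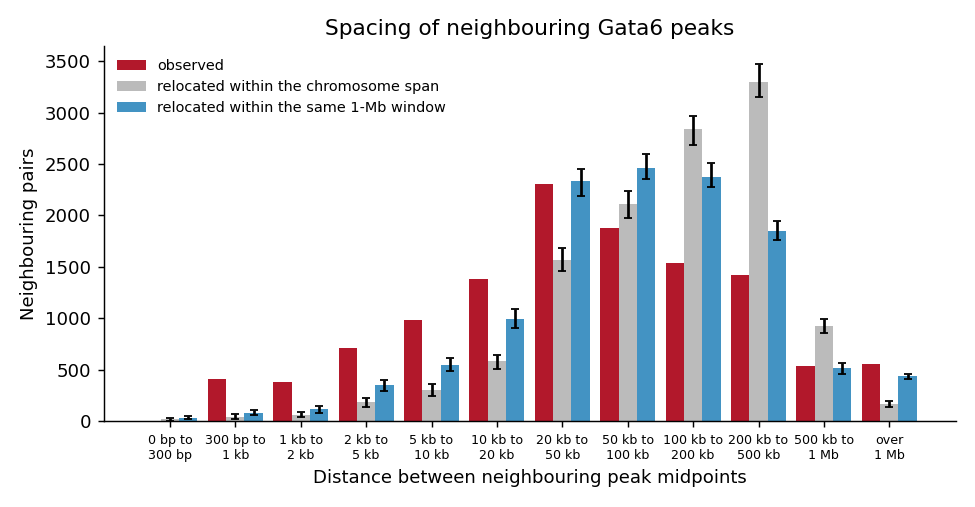
Number of neighbouring peak pairs by the distance between their midpoints: observed (red), and the mean of 1000 relocations within the chromosome span (grey) or within the same 1-Mb window (blue), with bars from the lowest to the highest relocation. Observed pairs exceed both relocations at distances from 300 bp to 20 kb, with none under 300 bp.

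Peaks were concentrated in parts of most chromosomes. In 53 windows of 1 Mb, on 17 chromosomes, there were 20 or more peaks, and at most 1 window reached that number in any relocation within chromosome spans (permutation p = 0.002). When peaks were moved only within their own 5-Mb windows, a mean of 7.16 windows and at most 15 reached it, a 7.40-fold excess (permutation p = 0.002, adjusted p = 0.00225). The 53 windows held 1253 peaks (10.3%). Chromosome 11 had 9 of them and chromosome 6 had 7, and none lay on chromosomes 12, 14 or X. The fullest window was on chromosome 7 from 119000001 to 120000000, with 39 peaks between 119022678 and 119967321, 7.49 times the density of that chromosome. It was followed by chromosome 5 from 91000001 to 92000000 (32 peaks), chromosome 1 from 137000001 to 138000000 (31 peaks), chromosome 7 from 87000001 to 88000000 (30 peaks) and chromosome 5 from 136000001 to 137000000 (29 peaks). A window on chromosome 8 from 129000001 to 130000000 tied with the last of these at 29 peaks. The fullest window of any relocation held 24 peaks within chromosome spans and 32 within 5-Mb windows.

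**Figure D3:**
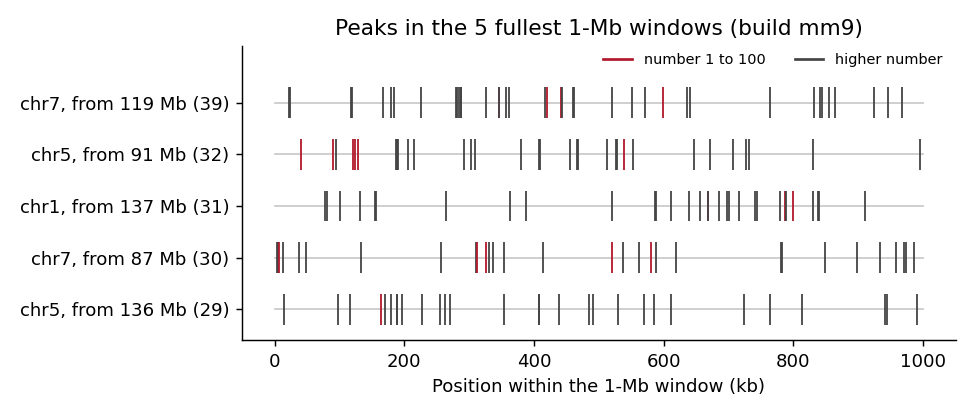
Positions of peaks (ticks) along the 5 fullest 1-Mb windows, with the number of peaks in brackets and peaks with name numbers 1 to 100 in red. The window on chromosome 7 from 119 Mb holds 39 peaks, 4 of them with numbers of 100 or lower.

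On a finer scale, 25 groups of 4 or more peaks, each within 5 kb of the next, were found, against a mean of 0.247 in relocations within chromosome spans and 2.60 within 1-Mb windows (permutation p = 0.002 for both). The groups with most members, named after their values were seen, had 5 peaks each, a size also reached in relocations, where the largest group had 5 peaks within chromosome spans and 8 within 1-Mb windows. They lay on chromosome 7 from 119279052 to 119288251, inside the fullest window, on chromosome 2 from 167656753 to 167666115 and on chromosome 11 from 16690195 to 16700830. Among groups of 4 peaks, the most compact was on chromosome 8 from 74936961 to 74939994, over 3.03 kb. A group of 4 on chromosome 4 from 124318535 to 124324116 included the peak with name number 4 of that chromosome.

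Long stretches held no peak. The longest were on chromosome X from 21371891 to 33471000 (12.1 Mb) and from 53718377 to 65748293 (12.0 Mb), and on chromosome 7 from 39056437 to 50699414 (11.6 Mb). There were 33 stretches of more than 5 Mb, of which 8 were on chromosome X. The longest stretch in relocations within chromosome spans averaged 5.21 Mb and reached at most 11.1 Mb (permutation p = 0.002). When peaks were moved only within their own 5-Mb windows, the longest stretch averaged 11.6 Mb and the observed one did not pass (permutation p = 0.47). Among the wider peaks alone it did not pass either (15.7 Mb against a mean of 10.3 Mb within chromosome spans, permutation p = 0.0719). Stretches of unassembled or repeated sequence were not told apart from sequence without Gata6 peaks.

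The name numbers were related to position and to width. When the peaks of each chromosome were sorted by number, the next peak lay at a higher position in 10900 of 12117 cases, against 50% of cases on average when positions were permuted 1000 times (permutation p = 0.001, the smallest they can give). Numbers therefore ran along the chromosome in repeated ascending series. Peaks with low numbers were wider: the median width was 155 bp for the 942 peaks numbered 1 to 50 and 135 bp for the 915 peaks numbered above 1500. The share that was 83 bp wide or narrower was 1.27% (95% interval 0.730 to 2.21) among the former and 16.7% (14.4 to 19.3) among the latter. Across all listed peaks Spearman's rho of number and width was -0.22 (permutation p = 0.0001, the smallest they can give). It was negative on all 20 chromosomes, from -0.32 to -0.17, each with an adjusted permutation p under the threshold of 0.05. These relations are across peaks, which are not independent replicates.

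Low numbers were mostly listed and high numbers mostly not. On the autosomes 1743 of the 1900 numbers from 1 to 100 were in the list (91.7%, 95% interval 90.4 to 92.9), 60.7% (58.5 to 62.9) of those from 301 to 400 and 38.3% (36.1 to 40.5) of those from 601 to 700. In all, the highest numbers summed to 36502 over the 20 chromosomes, of which 33.2% were listed.

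Peaks with a neighbour within 5 kb had lower name numbers. Their mean percentile among the numbers of their chromosome was 46.1 ± 28.0 (SD, 2811 peaks), against 51.3 ± 29.0 (SD, 9326 peaks) for peaks without one, a difference of -5.14 percentile points (permutation within chromosomes, adjusted p = 0.00015). Of the clustered peaks 28.4% were among the lowest 25% of the numbers of their chromosome, against 23.9% of the others (permutation, adjusted p = 0.00015). Both adjusted values rest on the smallest p that the permutations can give. Single peaks were permuted, although clustered peaks come as neighbours. Likeness of numbers between neighbouring peaks, not tested here, could make these p-values too small. Their widths differed by -0.04 bp, which did not pass (132.8 against 132.9 bp, permutation, adjusted p = 0.961).

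Chromosome 10 stood apart in its name numbers. It had 690 listed peaks and a density of 5.51 per Mb, within the range of the other autosomes, but its numbers ran to 4055, so that 17.0% were listed, against 27.5 to 41.5% on the other 18 autosomes. Up to the 90th percentile of the listed numbers the share was 20.1%, against 47.3 to 55.9%, and up to a number equal to the count of listed peaks it was 46.2%, against 66.0 to 72.1%. Its unlisted numbers were not spread evenly. Of the 3098 unlisted numbers that could be placed between listed peaks, 61.9% fell between 100000001 and 120000000, a segment with 101 of the listed peaks (14.6%), a ratio of 4.23. In the fullest 20 Mb of the other autosomes this ratio was 0.767 to 1.68. The fullest single Mb, from 117000001 to 118000000, held 201 placed numbers, against a median of 10.1 per Mb on chromosome 10 and at most 54.3 in any Mb of the other autosomes, reached on chromosome 19.

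**Figure D4:**
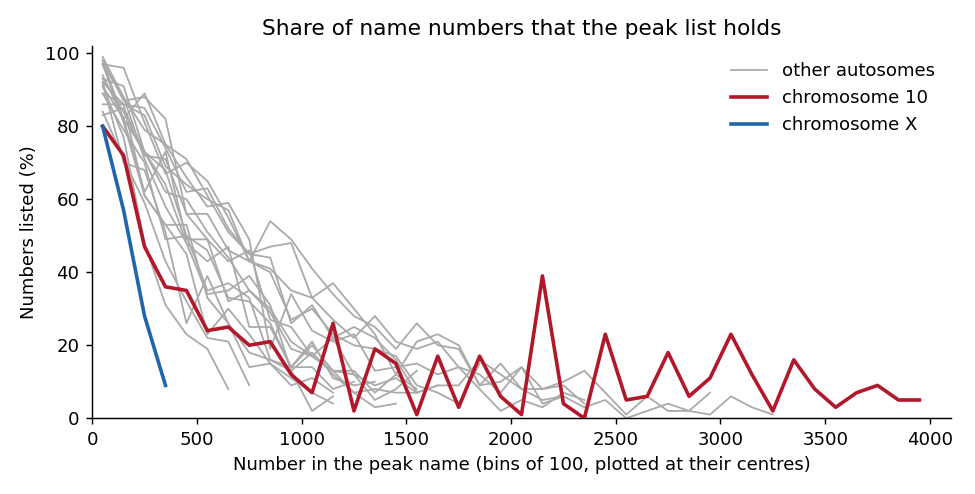
Percentage of name numbers, in bins of 100, that occur in the peak list, for chromosome 10 (red), chromosome X (blue) and the other autosomes (grey). Chromosome 10 is close to chromosome 14 for numbers 201 to 300 (47% against 48%) and above it for 301 to 400 (36% against 31%), and it continues to number 4055, against at most 3351 on the other autosomes.

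**Figure D5:**
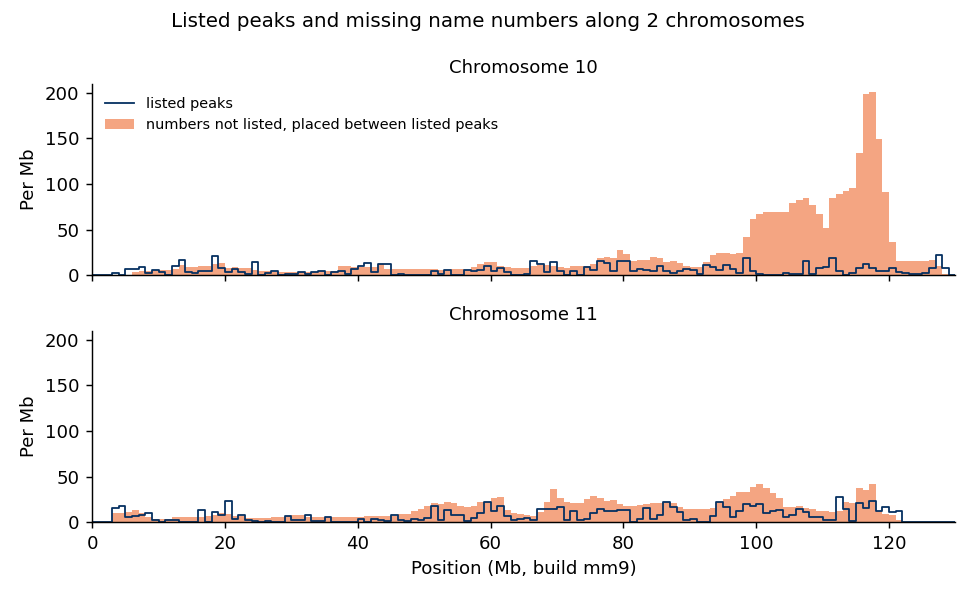
Listed peaks (dark line) and unlisted name numbers placed between listed peaks (orange bars) per Mb along chromosomes 10 and 11. Unlisted numbers on chromosome 10 are concentrated between 100 and 120 Mb, with a maximum of 201 in the Mb that starts at 117000001.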

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

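The list holds no values per library, so no library could be left out, and no paired analysis was possible because no values per replicate were at hand. The tests of pairs within 5 kb and of 1-Mb windows against relocation within chromosome spans, and the distances of 1 and 20 kb, were set before the data were examined. So were the autosome, merged-peak and wider-peak settings for the chromosomes, although the density test they were applied to was chosen after the data were seen, as were the remaining tests and settings. Of 36 alternative values, 25 kept the direction and the call or size. With a single setting changed at a time, the excess of close pairs stayed between 2.55-fold and 6.43-fold under 7 settings, and every one passed its relocation test. With distance and setting changed together the range was wider. The excess was 1.81-fold for pairs within 20 kb relocated within 1-Mb windows, and 7.05-fold for pairs within 1 kb among the wider peaks. Both passed (permutation p = 0.002 for each). The number of chromosomes apart from the others was 5, but 3 with autosomes only, where chromosome X is absent by construction and chromosome 6 did not pass, and 15 with an exact binomial test over peaks, which also made 215 calls in 400 simulated tests without an effect. The number of 1-Mb windows with 20 or more peaks was 53, but 2 among the wider peaks, which are fewer by construction. The width difference between clustered and isolated peaks passed in no setting: it was -0.04 bp, and reversed to 1.19 bp with neighbours within 1 kb, 0.35 bp within 20 kb and 0.23 bp without chromosome 10, and the cause was not tested. The share of unlisted numbers in the fullest 20 Mb of chromosome 10 was 61.9%. With numbers over 1000 or over 300 only it was 60.0% to 62.3%. With the wider peaks alone it was 51.1%, but narrower listed peaks then counted as unlisted, so this value is not comparable. The alternatives on promoters, transcription start sites, gene lists, motifs, sequence content and chromosome length were not run, for want of a genome of build mm9. Library depth limits which sites reach the list at all, and its effect could not be measured here.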

Other observations

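The tests on chromosome 10, on width and the relocations within 1-Mb windows were chosen after the data were seen, and the bounds for the relocations were set when the number of close pairs was known but no relocation had been run.

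The first pattern is the low share of name numbers listed on chromosome 10. Whether the numbers there are ordered differently stays open. Spearman's rho of number and width on chromosome 10 was -0.24, inside the range of the other chromosomes. This argues only against numbers that lack the relation to width or reverse it. The ranks of the listed peaks stay the same when extra intervals are numbered between them, so rho cannot exclude such a numbering. As the whole cause, extra copies of the entire chromosome are argued against. With the fullest 20 Mb of each autosome left out, 33.3% of numbers were listed on chromosome 10. This lay inside the range of the other autosomes, 28.9 to 48.4%, where the bound set for this test placed the absence of such copies. A part played by such copies stays open, since the segment was picked for its unlisted numbers and only chromosome 6 lay lower. Numbers that could not be placed, 267 on chromosome 10, were not counted in these shares. The density of listed peaks decided nothing (27.0 per 5-Mb window against 24.6 on the other autosomes, permutation p = 0.496). That 61.9% of the placed numbers fell in 20 Mb was seen before it was tested, so it describes where the unlisted numbers lie and is not independent evidence of a focal cause, and a difference in placing between the 249 listed peaks with numbers above 1500 and the other listed peaks of the chromosome did not pass (largest difference between their cumulative shares along the chromosome 0.0703, permutation p = 0.385). A hypothesis is a gain in copy number of this segment in the cells. Such a gain may have lifted local background over the calling threshold in the list that gave the names. A repeat-rich segment or a local filter stays as open. Read depth in the input library, not analysed here, would bear on these explanations but might not tell them apart.

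The second pattern is the closeness of neighbouring peaks. Uneven regional density does not account for all of it, since pairs within 5 kb were still 2.55 times as frequent as in relocations within 1-Mb windows, above the highest of 1000. Cutting of a wide site into several intervals stays open: pairs 2 to 5 kb apart were 2.05 times as frequent as in those relocations (713 against at most 406), above the bound set for this test, but a site several kb wide would also give such pairs and the list does not hold the width of whole sites. To be the whole cause, sites would have to span 10 kb or more, since the excess continued for pairs 10 to 20 kb apart (1381 against at most 1092). A biological hypothesis, not tested here, is that Gata6 may bind in clusters within regulatory regions, and overlap with open chromatin of the same cells, not used here, would test it against density that varies within less than 1 Mb.

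The third pattern is the narrowing of peaks at high name numbers. Among numbers above 1500 the share of peaks at 83 bp or narrower was 16.7% (95% interval 14.4 to 19.3). The upper limit lay under 50%, the bound set for chance overlap of unrelated intervals. Such overlap would give 50% only if all source intervals had 1 fixed width, which was not measured, so this explanation stays open. The width pattern may be that of 2 sets of fixed-width intervals intersected, in which the width falls as the centres move apart, and the numbers may rank intervals by strength with ties ordered by position. Both readings were drawn from the same values and no biological explanation was tested.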
